A study of Homo sapiens with 3 samples.

How the data were processed

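The values are whole UMI counts per gene and cell barcode, made by the authors with Cell Ranger 2.0.0 and bcl2fastq 2.17.1.14 and build hg19 per the submitters' processing notes, and no normalization had been applied to them as deposited. Each file listed 33694 genes by Ensembl identifier and symbol. That gene set resembles annotation of a later build than hg19, so no coordinates are given. The settings used to call cells and the use of strand are not given in the sources used here.

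The comparisons, fixed gene lists, naming markers, filters, rules for named genes and the alternatives listed in the last paragraph were chosen before the data were examined. The comparisons of the unnamed cluster with hiPSC-like cells and of hiPSC-like cluster 6 with cluster 1 were added afterwards, as were the alternatives that leave out hiPSC-like cluster 6, take endothelial-like clusters 2 and 5 singly, leave the markers of all classes out of the lists, leave out the interferon cluster, the early embryo cluster and the hiPSC-like cells of the library labelled SOX9-induced, or remove cells by doublet score up to the expected rate. The lists of early embryo, interferon response, RNA sensing, cartilage targets of SOX9 and white blood cell genes were also added after the data had been seen.

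Cells with at least 1000 genes and at most 10% mitochondrial UMIs (13 genes) were kept, which removed 18, 3 and 4 barcodes of the set 1, control and SOX9-labelled libraries. Scrublet, as run in scanpy, then called 5, 12 and 11 doublets, which is 0.351%, 0.527% and 0.341% against expected rates of 1.14%, 1.82% and 2.58%, so most doublets were left untreated. Removing cells of the highest scores up to the expected rate left 1409, 2264 and 3173 cells, where tied scores left the control as it was, and no list median or share that answers a comparison moved. Median mitochondrial shares were 5.60%, 3.87% and 3.32%, and ribosomal protein genes (86) took 33.8%, 38.5% and 32.0% of UMIs.

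Clusters of set 1 were found on genes whose Ensembl identifier ended in an odd digit and that were in none of the fixed lists, and 17077 genes were held out. Counts were scaled to 10000 per cell and log-transformed, 2000 highly variable genes were scaled, and Leiden clusters were drawn at resolution 0.5 from 15 neighbours on 30 principal components with seed 0. Set 2 was clustered in the same way. A cluster was named after a class (12 classes) when at least 3 of its markers reached 10 CPM and 25% of their highest cluster and its leading 10 genes did not point to another class. The classes of set 1 were hiPSC-like (clusters 1, 6, 7 and 8), endothelial-like (clusters 2 and 5), fibroblast-like (cluster 3) and unnamed (cluster 4). Interferon-induced genes led endothelial-like cluster 2 and a hiPSC-like cluster of set 2, and 3 were among the leading 10 genes of an unnamed cluster of set 2.

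UMIs were summed over the cells of a library or class and divided by their total to give CPM. Ratios carry exact conditional binomial (Clopper-Pearson) 95% intervals, CPM exact Poisson intervals and shares exact binomial intervals. A count of 0 was set to 3 over the group, and such ratios are bounds. Fixed lists (25, holding 496 symbols, of which 495 were matched, 3 by an older name, and ESRG was not) were read on members with at least 20 UMIs over both groups. Each median was set against 10000 random lists matched on mean expression. In the comparisons between classes of set 1 the fixed lists and the named rises and falls were read only on genes held out of the clustering. Markers of the hiPSC, endothelial and fibroblast classes were left out there too. This departs from the plan, which left out the naming markers of all classes, and lists read in that way are an alternative added after the data had been seen. Genes named were, among those with at least 50 CPM in the higher group and 100 UMIs, the 8 highest and 8 lowest by ratio and the 4 largest rises and falls in CPM, leaving out clone-based names, mitochondrial genes and XIST and Y-linked genes. From each list the highest, the lowest and the 2 members with most UMIs were eligible to be named, along with the naming markers and the induced factors. Not every gene picked in this way is named in the text. The named rises and falls were drawn from 15608 genes for the library labelled SOX9-induced, 7218 for endothelial-like, 7187 for fibroblast-like, 7123 for unnamed and 15097 for the background comparison. The shift of all genes was the median log2 ratio over genes with at least 50 UMIs in both groups.

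The procedure was tested on simulated data in which 200 genes were changed. Changes of 3-fold and 8-fold were called in 25 of 25 genes each way, and changes of 1.5-fold in none. At 2-fold, the limit of the rule, 7 rises and 14 falls of 25 were called in the set 2 design and 14 and 13 in the endothelial-like design. Unchanged genes were called in 53 of 15373 and 55 of 6816 cases, and 95.6% and 95.4% of intervals held the true ratio. A pluripotency list set 4-fold lower came back at −2.02 (true −2.02) and −2.07 (true −2.01). A simulated mixture of 4 profiles gave 4 clusters with 1421 of 1421 cells in their own class, and a single profile of 630 cells gave 1 cluster. All simulated counts were drawn from pooled profiles with counting noise alone, without differences between cells of a class or between preparations. The simulations therefore check the procedure for counting error only, and do not show how well real classes are recovered.

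Alternatives were no cell filter, at least 2000 genes with at most 5% mitochondrial UMIs, doublets kept, median-of-ratios size factors, totals without mitochondrial and ribosomal protein genes, means of per-cell CPM, list members with at least 5 or 100 UMIs, a pseudocount of 1 CPM, resolutions of 0.25 and 1, 15 principal components, variable genes drawn from all genes, and thinning to 2500 UMIs or none. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.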

Results

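The data are single-cell RNA sequencing profiles of human induced pluripotent stem cells (hiPSCs) and of cells derived from them by forced expression of a transcription factor. All cells came from PGP1, an established hiPSC line. The factor was switched on with doxycycline, a tetracycline that turns on an inducible transgene, for 4 days per the labels. RNA was counted with the 10x Genomics droplet method, in which each captured RNA molecule carries a unique molecular identifier (UMI), so that the values are numbers of molecules per gene and cell.

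There were 3 libraries in 2 sets. Set 1 was a single library of cells that had been grown apart and pooled before loading: unmodified hiPSCs, cells induced with ETV2 and labelled endothelial, and cells induced with NKX3-2 and labelled fibroblasts. Set 2 was loaded as separate libraries, uninduced control hiPSCs and cells labelled SOX9-induced oligodendrocytes. The set 1 library held 1444 cell barcodes and 32803969 UMIs, with a median of 20326.5 UMIs per cell. The control library held 2279 barcodes and 29925667 UMIs (median 11793), and the library labelled SOX9-induced held 3228 barcodes and 33795728 UMIs (median 10035.5). After filtering, 1421, 2264 and 3213 cells remained. No group had replicates, so no test between groups was possible, and no interval given here covers the spread between preparations: those of counts, ratios and shares cover counting error, and those of list medians the spread between genes. A gene is said to have risen or fallen where its CPM (its UMIs divided by all UMIs of the group and scaled to a common total) differed at least 2-fold and the 95% interval of the ratio excluded 1, which is a rule of size and not a test.

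The first question was whether the named factor was on in the cells that the labels say were induced with it. ETV2 (ENSG00000105672), an ETS-family factor needed for the formation of blood vessels and blood, stood at 180.8 CPM (95% Poisson interval 170.7 to 191.2; 1211 UMIs) in the endothelial-like cells of set 1, against 6.62 CPM in its hiPSC-like cells and 0.674 CPM in the control library. NKX3-2 (ENSG00000109705), a homeobox factor of the skeletal and gut mesenchyme, stood at 415.4 CPM (397.5 to 433.8) in the fibroblast-like cells and at 308.7 CPM (293.8 to 324.2) in a cluster of set 1 that received no name, against 5.01 CPM in the hiPSC-like and 5.52 CPM in the endothelial-like cells. SOX9 (ENSG00000125398), a factor of cartilage and of glial precursors, was lower in the library labelled SOX9-induced, at 1.88 CPM (1.44 to 2.40; 63 UMIs) against 4.24 CPM (3.53 to 5.05; 126 UMIs) in the control hiPSCs, a ratio of 0.442 (0.321 to 0.603). Its highest level was in the unnamed cluster of set 1, at 20.9 CPM (17.2 to 25.2). Because the transcript of the named factor was not raised, that library is called the library labelled SOX9-induced throughout, and directions drawn from it follow that label.

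Shares of cells gave the same order for ETV2 and NKX3-2. After each cell was thinned to 5000 UMIs, an ETV2 UMI was found in 41.3% of endothelial-like cells (exact binomial interval 36.2% to 46.5%) and in 1.75% of hiPSC-like cells, whose median depths before thinning were 14844 and 22027 UMIs. An NKX3-2 UMI was found in 78.4% of fibroblast-like and 71.2% of unnamed cells, and in 2.95% of endothelial-like cells, a class not labelled as induced with it. SOX9 UMIs were found in 1.64% of control cells and 1.28% of cells of the library labelled SOX9-induced, where 66 and 160 shallower cells were left out. Without thinning these shares were 66.2%, 8.41%, 94.4%, 91.2%, 9.92%, 5.30% and 1.87% in the order given. Counts at the end of a transcript need not include a transgene that lacks the native end, so the level of a factor limits what its labels can be checked against. NKX3-2 was not held out of the clustering, whereas ETV2 and SOX9 were.

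**Figure D1:**
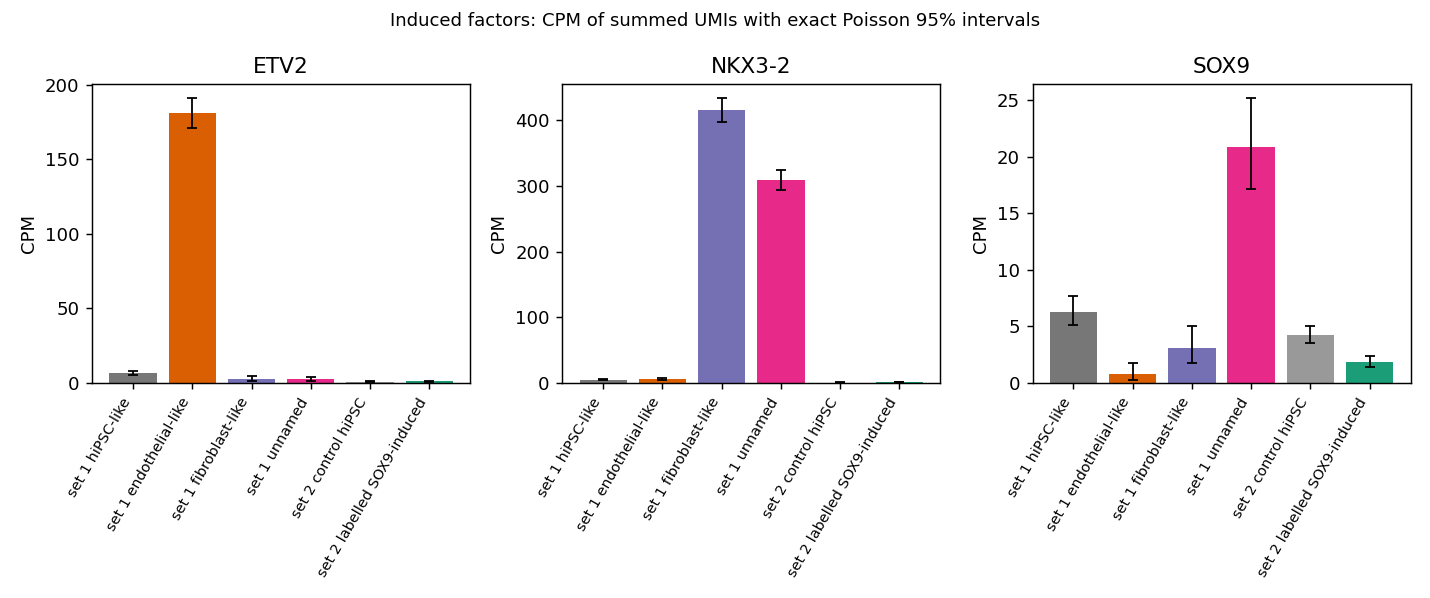
Level of the induced factors ETV2, NKX3-2 and SOX9 in each library of set 2 and each class of set 1, in CPM with 95% Poisson intervals. ETV2 was highest in the endothelial-like cells (180.8), NKX3-2 in the fibroblast-like cells (415.4), and SOX9 in the unnamed cells (20.9), with 1.88 in the library labelled SOX9-induced.

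The comparison within set 2 asks how cells labelled SOX9-induced differ from uninduced hiPSCs. Genes of the pluripotent state were lower in the library labelled SOX9-induced, where 25 of 28 measured members of the pluripotency list fell, none rose and 3 did neither. The list's median log2 ratio was −3.13 (interval −3.58 to −2.14), below all 10000 random lists of matched expression (percentile 0). POU5F1, a core factor of pluripotency, stood at 180.9 CPM against 1934 CPM in the control, TDGF1, a co-receptor for NODAL, at 9.95 against 353.7, and TERF1, a telomere protein abundant in hiPSCs, at 95.7 against 1322. The RNA-binding proteins LIN28A (265.8 against 347.1 CPM) and LIN28B (85.5 against 57.3 CPM) did neither.

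Epithelial genes were also lower. Of 19 measured members 13 fell, 1 rose and 5 did neither, with a median of −3.27 (−5.93 to −0.71). CDH1 (ENSG00000039068), which encodes E-cadherin, was at 0.417 against 52.2 CPM, and the vesicle protein RAB25 at 0.536 against 83.6 CPM. The keratins KRT8 and KRT18 had ratios of 1.12 and 0.893 and did neither.

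Genes of fibroblasts and of contractile cells were higher. In the fibroblast list 21 of 31 measured members rose, 3 fell and 7 did neither, with a median of 2.14 (0.35 to 2.42; percentile 100). LUM (ENSG00000139329), the matrix proteoglycan lumican, was at 85.5 CPM with no UMI in the control, at least 847-fold higher against a floor of 3 UMIs over the group. COL1A1 and COL1A2, the chains of type I collagen, had ratios of 17.2 and 11.8, the filament protein VIM 10.5 and the galectin LGALS1 24.2, while FSTL1 fell with a ratio of 0.467 and COL3A1 had 5 UMIs against 0. In the smooth muscle list 9 of 16 rose, 1 fell and 6 did neither, with a median of 1.74 whose interval reached from −0.54 to 3.39. ACTA2 (ENSG00000107796), the smooth muscle actin, was at 305.7 against 1.72 CPM, a ratio of 178.0 (135.3 to 239.2). TAGLN had a ratio of 10.5 and the myosin MYH11 of 18.0, and RGS5 fell with a ratio of 0.235.

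The label names oligodendrocytes, so genes of that lineage were read as their own lists. Of 10 measured members of the oligodendrocyte lineage list 8 fell and 2 rose, with a median of −2.25 (−3.91 to 1.07). OLIG1 had 0 UMIs against 14, OLIG2 0 against 1 and SOX10, a factor of glia, 3 against 10. PTPRZ1, a phosphatase of glial precursors, had a ratio of 0.121 and TCF7L2 of 0.418, and BCAS1 rose to 0.685 CPM, with 23 UMIs against 2. Only 10 of the 20 fixed members reached 20 UMIs, and with 100 UMIs asked for the number of members that fell was 3. In the myelin list 6 of 14 fell, 3 rose and 5 did neither, with a median of −0.51 (−3.46 to 1.17). MBP, a structural protein of myelin, was at 1.64 against 17.2 CPM. CLDND1 rose with a ratio of 2.25, and QKI had a ratio of 1.38.

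Other neural lists did not move as a group in the upward direction. Of 15 astrocyte genes 11 fell, among them the gap junction gene GJA1 with a ratio of 0.334, and SLC1A3, a glutamate transporter, rose with a ratio of 3.59; the median was −1.67 (−2.76 to −0.97). Of 14 neural crest genes 8 fell and 4 rose, with FOXD3 at a ratio of 0.0217 and the myelin protein gene PMP22 at 78.6, and a median of −1.35 (−2.71 to 5.28). Neural progenitor genes (4 rose and 3 fell of 11, median 0.49) and neuron genes (4 rose and 4 fell of 15, median −0.23) went both ways, with the transcriptional regulator DACH1 at a ratio of 39.2, ZIC2 at 0.00761 and the neuronal splicing regulator RBFOX3 at 0.0168.

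Cartilage genes, which include direct SOX9 targets in cartilage, went both ways with a median above 0. Of 18 measured members 10 rose, 6 fell and 2 did neither, with a median of 1.68 (−1.97 to 2.80; percentile 100). COL11A1 had a ratio of 33.4, COL2A1, the main collagen of cartilage, was at 48.5 against 3.44 CPM, and COL9A1 fell with a ratio of 0.221. At 100 UMIs per gene 6 members rose.

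Among other lists, p53 target genes rose in 10 of 16 members and fell in none (median 1.11, 0.24 to 1.61), with the cell cycle inhibitor CDKN1A at 360.9 against 22.3 CPM and the stress cytokine GDF15 at a ratio of 17.1. Cholesterol synthesis genes rose in 12 of 18 and fell in 1 (median 1.35, 0.62 to 1.99), with MSMO1 at a ratio of 6.18, FDPS at 2.76 and CYP51A1 at 0.213. Stress genes rose in 7 of 16 and fell in 2, with GADD45B at a ratio of 16.7. Unfolded protein response genes fell in 5 of 17 and rose in 1, with the glutathione-degrading enzyme CHAC1 at a ratio of 0.0670. Glycolysis genes fell in 4 of 16, among them the mitophagy receptor BNIP3 at a ratio of 0.0648, and rose in 1, PKM. Cell cycle lists hardly moved: 2 of 26 S phase genes rose and 2 fell, and none of 26 G2/M genes did either. Endothelial genes fell in 10 of 18 and rose in 4 (median −1.36), endoderm genes fell in 3 of 5 and rose in 1, blood genes rose in 5 of 10 and fell in 2, arterial genes rose in 3 of 11 and fell in 4, venous and lymphatic genes rose in 4 of 9 and fell in 2, mesoderm genes rose in 3 of 9 and fell in 3, and Notch pathway genes rose in 2 of 10 and fell in 2.

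The genes with the highest ratios of all were led by ANKRD1 (ENSG00000148677), a target of mechanical and YAP signalling, at 310.7 against 0.135 CPM, a ratio of 2307 (900.7 to 8468). C4orf26, an enamel matrix gene, was at 53.2 CPM against a single control UMI, a ratio of 1579.5 (283.1 to 62423). EMP1 had a ratio of 545.7, KRT81 was at least 513-fold higher against the floor, and the growth factor BMP4 had a ratio of 94.3. The lowest ratios belonged to FOXD3-AS1 (0.00538), RAB25 (0.00641), the triadin gene TRDN (0.00663), LINC00458 (0.00769), the metallothionein MT1H (0.00779), CDH1 (0.00798), the splicing regulator ESRP1 (0.00999) and ZSCAN10 (0.0122). The largest rises in CPM were those of the nuclear RNA MALAT1 (14599 against 4837), the ferritin chain FTH1 (8350.3 against 2503) and the thymosin TMSB4X (9909 against 4324). FTL was at 9077 against 6224 CPM. RPL3, RPS18, RPL12 and RPL13A lost most CPM without passing the rule, at ratios of 0.550, 0.762, 0.578 and 0.736. FOXD3-AS1 is an antisense RNA, and the sources used here do not say whether strand was used. Metallothionein and ribosomal protein genes have near-identical copies, so their reads may be shared.

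**Figure D2:**
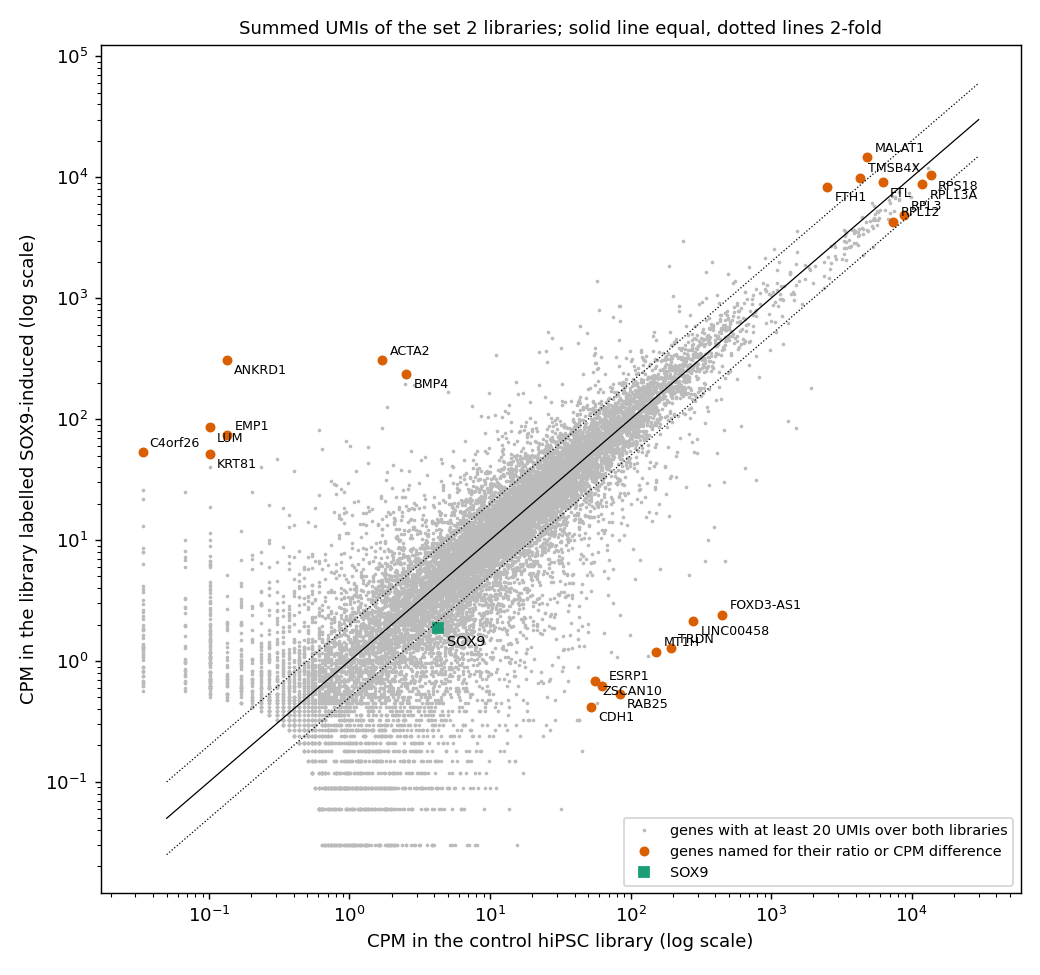
Each point is a gene, placed by its level in the control hiPSC library and in the library labelled SOX9-induced, in CPM on log axes. POU5F1 lies at 1934 and 180.9, ACTA2 at 1.72 and 305.7, and COL1A1 at 7.41 and 127.4.

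Clusters of set 2 described what these libraries held. All control cells fell in clusters named hiPSC-like. In the library labelled SOX9-induced 77.6% of cells (76.1% to 79.1%; 2494 cells) lay in clusters named fibroblast-like, 20.8% (19.4% to 22.2%) in unnamed clusters, the larger of which tied between fibroblast and smooth muscle markers and had the interferon-induced IFI6, EPSTI1 and IFI27 among its leading genes, and 1.62% (1.21% to 2.12%; 52 cells) in hiPSC-like clusters. Of the latter, 17 cells lay in a cluster led by interferon-induced genes, and they carried fibroblast markers too, with LUM at 50.5 and COL1A2 at 256.2 CPM beside POU5F1 at 508.5 CPM. No LUM UMI was counted in the others, so the share of hiPSC-like cells is an upper value. No cluster met the rule for an oligodendrocyte-like name. With 1 library per group, a cluster made mostly of 1 library may be that library and not a cell type. The median log2 ratio over all well-counted genes was 0.02, and relative to it the rises became 20 in the fibroblast, 9 in the p53 target and 3 in the neural progenitor list.

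A background for these values is the difference between the hiPSC-like cells of set 1 and the control library of set 2. The former were named by their expression, so some may be induced cells that kept hiPSC markers, and cluster 6, 110 of these 630 cells, carried ETV2 at 23.8 CPM. The pluripotency list had a median of 0.06 (−0.11 to 0.22), with 2 of 28 members higher and 3 lower. POU5F1 was at 1459 against 1934 CPM. None of 26 G2/M genes and 1 of 26 S phase genes, TYMS, passed the rule. The fibroblast list had a median of 0.71 (0.46 to 0.80), with 6 of 28 higher and none lower, among them VIM at 226.5 against 82.7 CPM and TNC at a ratio of 18.7. Without hiPSC-like cluster 6, left out after the data had been seen, that median was 0.26 and no member was higher.

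Other lists stood apart between the preparations as well. The mesoderm list was higher in 5 of 10 members (median 1.35), with MIXL1 at a ratio of 11.6, and the endothelial list in 11 of 22 (median 0.95). The mesoderm list rested largely on hiPSC-like cluster 6 and the endothelial list in part. Without that cluster no mesoderm gene was higher (median −0.49), while 5 endothelial genes were still higher (median 0.51). MIXL1 then had a log2 ratio of −0.68 (−1.73 to 0.26). For CDH5, 24 UMIs were counted in the set 1 cells and none in the control, in a library where endothelial-like cells carried 309.9 CPM. The smooth muscle (6 higher and 2 lower of 16), cartilage (5 and 1 of 15), stress (5 and 2 of 16) and cholesterol (2 and 0 of 18) lists had medians of 0.29, 0.69, 0.58 and 0.48, the p53 target (3 and 0 of 16), oligodendrocyte lineage (1 and 1 of 11) and myelin (1 and 2 of 14) lists −0.04, 0.26 and −0.06, and the glycolysis list (0 and 4 of 16) −0.44. The remaining lists lay between −0.18, for the unfolded protein response, and 0.84, for neural progenitor genes.

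TMEM160 (29.2), the neuropeptide GAL (25.4), C17orf89 (18.1), SNHG7 (8.95), COPRS (8.80), ID1 (8.62), PRELID1 (7.75) and MARCKSL1 (7.62) had the highest ratios between these preparations. IFIT1, an interferon-induced gene, had the lowest (0.0619), but 2273 of its 2404 control UMIs lay in 49 cells of a single cluster, and the main control clusters stood at 4.39 and 4.64 CPM against 5.01 CPM in set 1. It was followed by TXNIP (0.145), CCDC144NL-AS1 (0.194), LINC00458 (0.206), BNIP3 (0.299), CCNG1 (0.330), TRDN (0.330) and CCNC (0.345). RPL3 had a ratio of 0.439 and FTH1 of 1.82. The control library is the denominator here and in the comparison within set 2. A gene that moves the same way in both may therefore owe some or all of this to that library. For LINC00458 and TRDN it can be some only, as their ratios within set 2 were far below those given here. RPS2, RPL41 and RPS27 gained CPM and RPS18, RPL12 and RPS3A lost CPM without passing the rule. This comparison also holds whatever differed between the sets, and it is a single pair of preparations.

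**Figure D3:**
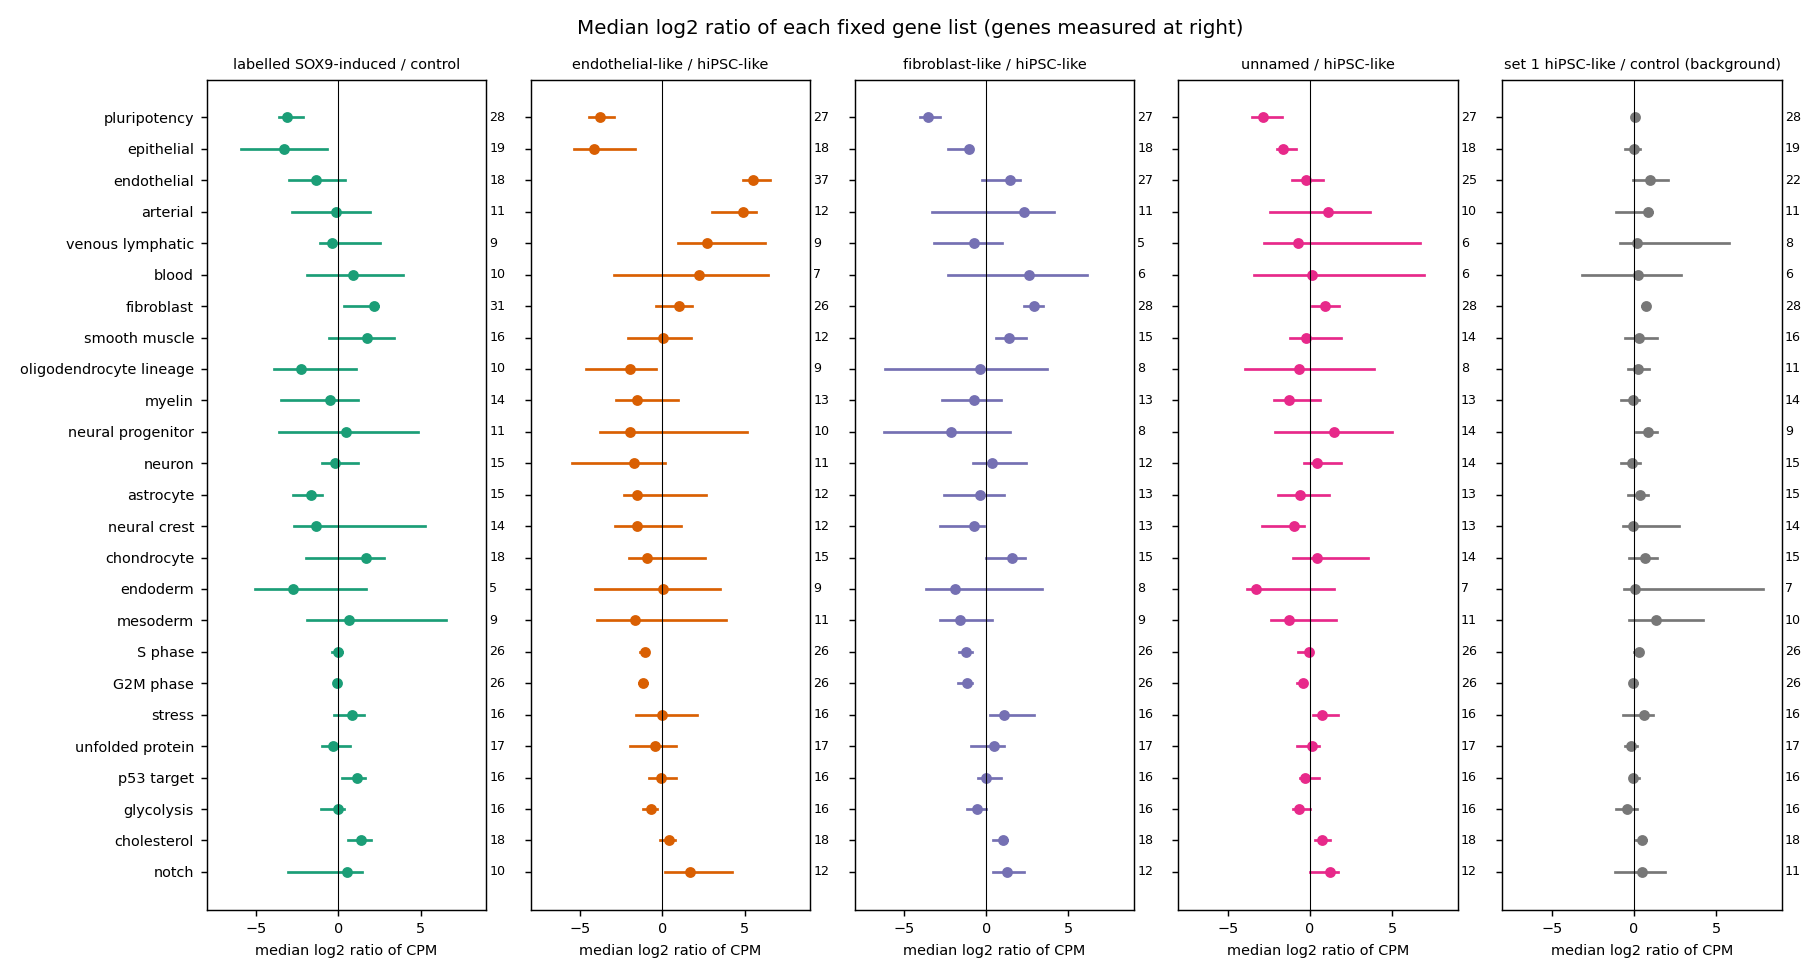
Median log2 ratio of each fixed gene list in each comparison, with its 95% interval from the order of the members. The pluripotency list lies at −3.13 in the library labelled SOX9-induced and at 0.06 in the background comparison of set 1 hiPSC-like cells with the control.

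Set 1 holds no map from cells to the 3 kinds of cells pooled, so its cells were grouped by expression and named by fixed markers. hiPSC-like clusters held 630 cells, 44.3% of the library (exact binomial interval 41.7% to 47.0%). Endothelial-like clusters held 373 cells, 26.2% (24.0% to 28.6%), the fibroblast-like cluster 213 cells, 14.99% (13.2% to 17.0%), and the unnamed cluster 205 cells, 14.4% (12.6% to 16.4%). The last 2 together made 29.4% (27.1% to 31.9%). The unnamed cluster had 4 fibroblast markers on, but its leading genes held a cartilage marker and none of the fibroblast class, and at a lower clustering resolution it joined the fibroblast-like cells. With a filter of at least 2000 genes and at most 5% mitochondrial UMIs, 552 cells remained and the endothelial-like share became 56.9%. Those shares count what was loaded and kept, and do not measure how well each induction worked.

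The comparison of endothelial-like with hiPSC-like cells asks what ETV2-induced cells express. All 37 measured members of the endothelial list rose, with a median log2 ratio of 5.53 (4.93 to 6.56; percentile 100), and so did all 12 measured arterial genes, with a median of 4.92 (3.01 to 5.69). The sialomucin EMCN (ENSG00000164035) was at 53.6 CPM against a single hiPSC-like UMI, a ratio of 833.6 (148.7 to 33015). GNG11 was at 1370.0 against 16.1 CPM and the receptor partner RAMP2 at 1315 against 28.5 CPM, and NOS3, the nitric oxide synthase of endothelium, had the lowest ratio of the list, 3.87. The Notch ligand DLL4 had a ratio of 297.2 (81.4 to 2467) on 2 hiPSC-like UMIs, EFNB2 of 18.5 and UNC5B of 4.18. Venous and lymphatic genes rose in 7 of 9, with NR2F2 at a ratio of 191.6 (52.2 to 1595), again on 2 hiPSC-like UMIs, and PDPN fell with a ratio of 0.0697. Notch pathway genes rose in 8 of 12 and fell in 2, with MFNG at a ratio of 53.4 and NOTCH1 at 3.66.

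Pluripotency genes fell in 25 of 27 members, with a median of −3.76 (−4.47 to −2.91), and 1 rose, GDF3, with a ratio of 3.84. SOX2, a core pluripotency factor, was at 1.64 against 150.2 CPM, and NODAL had a ratio of 0.00948 on a single UMI (0.000239 to 0.0533). Epithelial genes fell in 17 of 18 (median −4.18, −5.36 to −1.66), with CDH1 at 3 UMIs and a ratio of 0.00832 (0.00171 to 0.0244) and KRT8 at 0.317. S phase genes fell in 17 of 26 and rose in none (median −1.08, −1.33 to −0.94), and G2/M genes fell in 16 of 26 and rose in none (median −1.18, −1.40 to −0.90). The replication helicase subunit MCM3 had a ratio of 0.289 and the ubiquitin-conjugating enzyme UBE2C of 0.450, while BIRC5, at 0.984, did neither. The G2/M falls lay mostly in endothelial-like cluster 2: with cluster 5 alone, taken apart after the data had been seen, 3 G2/M and 9 S phase genes fell (medians −0.59 and −0.77), against 23 and 22 with cluster 2 alone (−2.01 and −1.61). The log2 ratio of UBE2C was −0.51 with cluster 5 alone, which does not pass the rule, and that of MCM3 was −1.51.

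Lists of other cell types were mixed. Fibroblast genes rose in 13 of 26 and fell in 2 (median 0.99, −0.35 to 1.80), with the proteoglycan BGN at a ratio of 61.2 and VIM at 13.7. Smooth muscle genes rose in 5 of 12 and fell in 3, and blood genes rose in 4 of 7 and fell in 2, with LAPTM5 at a ratio of 87.8. The oligodendrocyte lineage fell in 6 of 9 (median −1.95) and neuron genes in 7 of 11, and none of either rose. Myelin genes fell in 8 and rose in 2 of 13, neural progenitor genes fell in 6 and rose in 3 of 10, astrocyte genes fell in 7 and rose in 3 of 12, neural crest genes fell in 7 and rose in 3 of 12, cartilage genes fell in 7 and rose in 4 of 15, and mesoderm genes fell in 7 and rose in 3 of 11. Without any naming marker neural crest genes fell in 3 and rose in 3 of 8 and cartilage genes fell in 4 and rose in 4 of 11, and without hiPSC-like cluster 6 mesoderm genes fell in 2 and rose in 3. Endoderm genes rose in 2 of 9 and fell in 4, with SOX17, which endothelium also expresses, at a ratio of 14.8. Of the remaining lists, stress genes rose in 5 and fell in 4 of 16, unfolded protein response genes in 4 and 6 of 17, p53 targets in 2 and 2 of 16 and glycolysis genes in 1 and 4 of 16, and none of 18 cholesterol genes passed the rule.

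By ratio the leading genes after EMCN were MMRN1 (385.4), FCN3 (291.6), the gap junction gene GJA5 (229.9), ADGRF5 (213.6), the sphingosine phosphate transporter SPNS2 (198.7), the ETS factor FLI1 (169.7) and PLVAP (161.1). After CDH1 the lowest were FOXD3-AS1 (0.00914), FOXH1 (0.0101), MT1G and SOX2 (each 0.0109), ZIC2 (0.0116), LINC00678 (0.0149) and MT1H (0.0156). TMSB10 (7738 against 2089 CPM), MALAT1 (9870.4 against 4292) and the interferon-induced ISG15 (4943 against 164.3) gained most CPM with a rise, as did TPT1, whose ratio of 2.04 became 1.95 relative to the median of all genes. EEF1A1, RPS2, RPLP1 and PTMA lost most CPM without passing the rule, the first 3 at ratios of 0.727, 0.792 and 0.874. The median of all well-counted genes was 0.06. The interferon-induced part of these genes came mostly from endothelial-like cluster 2.

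The comparison of fibroblast-like with hiPSC-like cells asks the same of the cells with NKX3-2. The median log2 ratio of all well-counted genes was 0.34 here, so list counts and medians are given relative to it, while gene ratios are of CPM unless stated. In the fibroblast list 23 of 28 measured members rose and none fell, with a median of 2.56 (1.95 to 3.14). LGALS1, a galectin, was at 1304 against 32.7 CPM and VIM at 2529.7 against 226.5 CPM, and TNC had a ratio of 0.687 and did neither. In the pluripotency list 24 of 27 fell and none rose, with a median of −3.86 (−4.36 to −3.12). TERF1 had a ratio of 0.0308 and the deubiquitinase USP44 of 0.0162, whereas GAL, at 663.8 against 743.5 CPM, did neither. Epithelial genes fell in 13 of 18 and rose in none (median −1.41, −2.64 to −1.22).

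S phase and G2/M genes each fell in 20 of 26 and rose in none, with medians of −1.60 (−2.01 to −1.20) and −1.53 (−2.07 to −1.21). By CPM alone, as for the endothelial-like cells, 15 and 16 fell, with medians of −1.25 and −1.18. HELLS, a chromatin remodeller of replicating cells, had a ratio of 0.187 and UBE2C of 0.291. Smooth muscle genes rose in 7 of 15 and fell in 2 (median 1.07), with TAGLN at 1136 against 212.5 CPM and RGS5 at a ratio of 0.0548. Cartilage genes rose in 8 of 15 and fell in 3 (median 1.22, −0.33 to 2.02), with SOX6 at 8.99 against 0.450 CPM and COL9A3, a naming marker, at a ratio of 6.74. Without any naming marker cartilage genes rose in 5 of 11 and fell in 2 (median 0.62, −1.05 to 2.47), and smooth muscle genes rose in 4 of 10 and fell in 1 (median 0.61, −0.02 to 3.19). Notch genes rose in 6 of 12 and fell in none, with the effector HES1 at 417.4 against 84.7 CPM. Stress genes rose in 7 of 16 and fell in none, with the phosphatase DUSP1 at a ratio of 22.0. Cholesterol genes rose in 4 of 18 (by CPM alone in 9) and fell in none, with INSIG1 at a ratio of 5.71.

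Endothelial genes rose in 13 of 27 and fell in 5 (median 1.10, −0.62 to 1.74), with CD34 at 15.7 against 1.03 CPM and FLT1 at a ratio of 0.0506. Arterial genes rose in 6 of 11 and fell in 3, and blood genes rose in 4 of 6 and fell in 1, with RUNX1 at a ratio of 49.5. Myelin genes fell in 7 of 13 and rose in 1, MYRF, at a ratio of 35.8, and oligodendrocyte lineage genes fell in 4 of 8 and rose in 2. The neural crest list fell in 8 of 13 members and rose in 1, the mesoderm list fell in 5 of 9 (by CPM alone in 5, and in 1 without hiPSC-like cluster 6), and the endoderm list fell in 5 of 8 and rose in 2. Neural progenitor genes fell in 4 and rose in 1 of 8, astrocyte genes fell in 5 and rose in 1 of 13, neuron genes fell in 3 and rose in 3 of 12, and venous and lymphatic genes fell in 3 of 5. Glycolysis genes fell in 6 and rose in 2 of 16, unfolded protein genes fell in 5 and rose in 3 of 17, and p53 targets fell in 2 and rose in 3 of 16.

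C4orf26 (ENSG00000174792) led by ratio, at 229.4 against 0.514 CPM (446.0, 225.6 to 1036), and high ratios were also found for the growth factor IGF2 (209.5; 1926 against 9.19 CPM), the cytokine IL11 (74.7), the deiodinase DIO3 (70.5), CCDC68 (68.6), GATA2 (68.5) and HSBP1L1 (63.4). FOXD3-AS1 (0.00200), MT1H (0.00823), LINC00678 (0.00895), LINC01356 (0.00964), MT1G (0.0128), ZIC2 (0.0133), PTPRZ1 (0.0144) and USP44 were lowest. MALAT1 (26627 against 4292 CPM), TMSB4X (19276 against 5471), FTL (16445 against 5703) and FTH1 (12794 against 4556) gained most CPM. EEF1A1, a translation elongation factor, lost most, with a ratio of 0.462, and RPS2, RPLP1 and RPS18 had ratios of 0.658, 0.685 and 0.685. SOX9 stood at 3.07 against 6.30 CPM, and its direction turned where the unnamed cluster was counted as fibroblast-like. It also turned with at least 2000 genes and at most 5% mitochondrial UMIs (log2 ratio 0.27, −1.01 to 1.42).

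The unnamed cluster shared the high NKX3-2 level and was compared with the hiPSC-like cells in the same way, a comparison added after it had been seen. Counts and medians are again relative to the median of all genes, which was 0.19. Pluripotency genes fell in 24 of 27 and rose in 1, LEFTY2 (median −3.07, −3.72 to −1.88), and epithelial genes fell in 14 of 18 (median −1.82). NANOG, a core pluripotency factor, had a ratio of 0.0147. Fibroblast genes rose in 12 of 28 and fell in 2, with a median of 0.70 (−0.05 to 1.53), POSTN at a ratio of 24.5 and VIM at 5.01. Neural progenitor genes rose in 8 of 14 and fell in 4 (median 1.25, −2.31 to 4.78), with NR2F1 at least 90.5-fold higher against the floor. Cartilage genes rose in 5 of 14 and fell in 4, with SOX6 at a ratio of 54.6 and COL2A1 at 11.3. COL2A1 is also the cartilage marker that kept the cluster from a fibroblast-like name, and without any naming marker 3 of 10 rose and 3 fell. S phase genes fell in 7 of 26 and G2/M genes in 7 of 26, and none of either rose. By CPM alone 4 S phase genes fell and 1 rose, and 3 G2/M genes fell. Notch genes rose in 5 of 12 and fell in none, arterial genes rose in 5 of 10 and fell in 2, and myelin genes fell in 9 of 13 and rose in 2. GATA2 (120.0), the protocadherins PCDH17 (96.7) and PCDH9 (83.1), BAHCC1 (53.7), ZEB2 (20.1), MN1 (17.4), MDFIC (17.3) and CPE (15.4) had the highest ratios, and MT1H (0.00386), MT1G (0.00840), LINC01356 (0.0136) and FOXD3-AS1 (0.0141) the lowest, followed by NANOG, LINC00678 (0.0174), the tetraspanin CD9 (0.0308) and USP44 (0.0448). MALAT1 (15609 against 4292 CPM) and TMSB10 (5098 against 2089) gained most CPM with a rise, while FTL and FTH1, at 1.78 and 1.88 relative to all genes, did neither. EEF1A1 (0.699), RPL15 (0.719), PTMA (0.679) and GAPDH (0.646) lost most CPM without passing the rule.

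In the comparisons between classes of set 1 the genes of the lists and those named by ratio or CPM difference had no part in the clustering, unlike NKX3-2. The genes named in the background comparison were not limited in this way. The markers of the hiPSC, endothelial and fibroblast classes were kept out of the lists, but those of the other classes, such as COL2A1, TAGLN, RGS5 and RUNX1, stayed in them. The named classes were still built from the same cells, so their contrast is sharper by construction than that of labelled samples. Levels in the hiPSC-like cells of set 1 can hold free RNA of the other cells of the same droplets.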

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

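The tests of explanations given here were all chosen after the results had been seen. These signals lie in clusters that were not set apart in the comparisons between libraries or classes, and each stood above the level in its control cells or above the limit that a count of 0 allows.

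In the library labelled SOX9-induced, 0.996% of cells (32 cells, 0.682% to 1.40%) formed a cluster led by genes of the early embryo. No control cell lay in that cluster, and the exact binomial interval of that share reaches 0.163%. The 15 early embryo genes summed to 5034.6 CPM there (4801 to 5277) and to under 7 CPM in each of the other clusters of set 2. That list was written after the clusters had been seen, so a high sum in this cluster was set by construction and describes it only. TRIM43 stood at 1242 CPM, CCNA1 at 886.8 and ZSCAN4 at 205.1. DUX4, the factor that switches such genes on, had 0 UMIs in the cluster and in the whole library. Its counts therefore do not show whether it was on. TRIM43, MBD3L2 and KHDC1L belong to families of near-identical genes, so the member that was expressed is uncertain.

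Technical explanations for that cluster were tested first. Doublets would carry more RNA, and the median depth was 10338.5 against 10028 UMIs in the other cells of the library, a ratio of 1.03 (bootstrap interval 0.886 to 1.15), which argues against them. Cells of another preparation would resemble it, but on held-out genes the profile correlated with the rest of its own library at r 0.944 and with the next closest group at 0.829 (2086 genes, across genes). Only the control library and the classes of set 1 were compared, so cells of a preparation outside these data could not be detected. That the cluster may follow from induction cannot be told apart from a chance of this culture, because its share of 0.996% against 0 comes from 1 library on each side.

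In set 1, interferon-stimulated genes summed to 10539.5 CPM (10436 to 10644) in endothelial-like cluster 2, against 344.1 CPM in hiPSC-like cells and 861.2 CPM in endothelial-like cluster 5. Against hiPSC-like cells all 16 measured members rose in cluster 2, with a median log2 ratio of 7.004 (3.40 to 7.38), and 10 of 14 rose in cluster 5, with a median of 2.27 (0.45 to 3.54). Members also rose in fibroblast-like cells, 12 of 15 with a median of 3.08 (summed CPM 1197), and in unnamed cells, where 8 of 14 rose and 2 fell with a median of 1.49 (451.1). Of these 16 genes 12, IFI6 among them, were not held out of the clustering, and the other 4 summed to 415.2 CPM in cluster 2, 41.2 in cluster 5 and 6.75 in hiPSC-like cells. Free RNA would spread over the droplets alike, and the ratio between these clusters of 12.2 (11.8 to 12.7) argues against it. White blood cells would bring their own genes, yet the median of 10 such genes was 2.27 CPM and PTPRC, carried by all white blood cells, stood at 0.803, with CD74 (110.0), which interferon also induces, and CD52 (11.5) the most abundant. Interferon set free within the culture may reach some cells and not others, and this cannot be told apart from a response within single cells, because cluster 5 held 8.17% of the level of cluster 2, above the hiPSC-like level and far below its neighbour.

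In hiPSC-like cluster 6 of set 1 (110 cells), ETV2 stood at 23.8 CPM (18.9 to 29.6; 33 cells with a UMI) against 1.73 CPM in cluster 1, the largest hiPSC-like cluster. Against cluster 1, mesoderm genes rose in 7 of 9 members and fell in 1 (median 3.77, −0.54 to 6.06), with MIXL1 at 79.3 against 1.00 CPM, and endoderm genes rose in 4 of 6 and fell in 1 (median 3.09, −2.91 to 6.98), with EOMES at 34.6 CPM against 0 UMIs and CER1 at 8.13 against 0.0911 CPM. Fibroblast genes rose in 14 of 24 and fell in none (median 1.21, 0.80 to 2.22). Chosen after their values were seen, NODAL stood at 64.8 against 1.46 CPM and APLNR at 23.2 against 0.364, and the cluster kept POU5F1 at 1188 CPM and NANOG at 65.9 CPM. Whether the cells with ETV2 are those with the other genes was left open, because a cell without a UMI may still express the gene. Cells with an ETV2 UMI were deeper (median 32509 against 24474 UMIs), which would raise their share with a UMI of another gene. A MIXL1 UMI was found in 11 of the 33 cells with an ETV2 UMI and in 32 of the other 77. For NODAL these counts were 14 and 49, for EOMES 8 and 35, for APLNR 9 and 8, and for GATA4 6 and 5. Depth may account for the higher shares of APLNR and GATA4, but not for the lower ones of MIXL1, NODAL and EOMES. No interval was computed for these shares, so counting error over only 33 cells was not excluded for any of them. No explanation of this cluster was tested.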

How the results depend on the processing

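No paired analysis was possible because each group holds 1 library. The alternatives that leave out hiPSC-like cluster 6, take a single endothelial-like cluster, leave the markers of all classes out of the lists or set cells of set 2 aside were chosen after the data had been seen, as were the doublet scores and the unnamed comparison. Among results that answer a comparison, 184 counts, 182 medians and 29 shares stayed within their limits over the alternatives, and 7, 9 and 21 did not. For other results 2857 counts, 1493 medians and 9080 values of single genes stayed, and 352, 16 and 1469 moved. A further 20 values of single genes turned direction, the same gene counting once for each comparison and alternative. Some of these 20 are bounds, where a group had no UMI and the floor was used.

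Every median that answers a comparison kept its direction under the alternatives tried, apart from the pluripotency list of the background comparison (−0.14 to 0.12). In the library labelled SOX9-induced pluripotency ranged from −3.43 to −2.15 and fibroblast genes from 1.11 to 2.22 over 11 alternatives. There cartilage genes ranged from 0.64 to 1.94 and oligodendrocyte lineage genes from −2.42 to −1.06. Endothelial genes in endothelial-like cells ranged from 4.86 to 6.31 over 18, and fibroblast genes in fibroblast-like cells from 2.14 to 3.17 over 16.

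With at least 2000 genes and at most 5% mitochondrial UMIs, set 1 kept 552 cells, and the shares became 28.6% hiPSC-like, 56.9% endothelial-like, 10.7% fibroblast-like, 3.80% unnamed and 14.5% for the last pair. Fibroblast-like pluripotency moved to −2.33, and the background to −0.14 for pluripotency and 1.137 for fibroblast genes, 14 of them higher. Log2 ratios turned for SLC16A3 (−0.26) and ZIC1 (−0.32) in endothelial-like cells, COL9A1 (0.033), OLIG2 (−0.25) and SOX9 (0.27) in fibroblast-like cells, and GFAP (0.18) and HBE1 (0.50) in the background. The values of ZIC1, GFAP and HBE1 are bounds, because 1 group had no UMI left and the floor was used, so they show no turn. Intervals of the other genes left the direction open, and the cause was not tested for them.

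Without the markers of any class, as planned, and not set against the median of all genes, cartilage genes in fibroblast-like cells rose in 5 and fell in 1 of 11 (median 0.97) and smooth muscle genes rose in 5 of 10 (0.96), and in unnamed cells cartilage genes rose in 3 of 10 (0.07).

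With members of at least 100 UMIs, fewer genes were measured by construction, and 3 oligodendrocyte lineage genes were lower, 6 cartilage genes higher and 3 background fibroblast genes higher. A pseudocount of 1 CPM shrinks ratios of weak genes by construction and gave 4 lower oligodendrocyte lineage genes, 4.86 for endothelial genes in endothelial-like cells and −2.63 for fibroblast-like pluripotency.

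At resolution 0.25 fibroblast-like cells made 29.4% and unnamed cells 0%, fibroblast genes moved to 2.14, and FABP7 (0.28) and SOX9 (0.96) turned, since the unnamed cells had joined the class. At resolution 1 these shares were 27.0% and 2.39%, SOX9 was 0.99, and background fibroblast genes had a median of 0.46 with 3 higher. With variable genes drawn from all genes the shares were 27.0% and 2.46%, fibroblast genes 2.21 and SOX9 1.07. In both settings the fibroblast-like class held 384 cells, with 34 and 35 cells left unnamed, against 213 and 205 in the main setting. Most unnamed cells had thus joined that class, as at resolution 0.25. At resolution 1, 26 cells were also named endoderm-like and 604 hiPSC-like, against 630 hiPSC-like cells in the main setting. Whether that moved the background was not tested.

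Without hiPSC-like cluster 6, which held most MIXL1, ETV2 and APLNR of its class, MIXL1 turned to 0.27 in endothelial-like, 1.63 in fibroblast-like and 2.92 in unnamed cells and to −0.68 in the background. APLNR turned to 0.57 and ETV2 to 0.62 in fibroblast-like cells, and to 0.89 and 0.41 in unnamed cells. The APLNR value in fibroblast-like cells is an upper bound, as no UMI was counted there and the floor was used. Intervals spanned 0 for APLNR in unnamed cells and for ETV2 in both classes, so no rise is shown. Those of MIXL1 in endothelial-like cells and in the background spanned 0 as well. Background fibroblast genes had a median of 0.26 with 0 higher. With endothelial-like cluster 5 alone CNP turned to −0.056; the cause was not tested.

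Depth sets the share of cells with a UMI by construction. At 2500 UMIs and without thinning it was 27.1% and 66.2% for ETV2 in endothelial-like cells, 61.0% and 94.4% for NKX3-2 in fibroblast-like cells, 50.7% and 91.2% in unnamed cells, 0.928% and 5.30% for SOX9 in control cells, and 0.530% and 1.87% in the library labelled SOX9-induced.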

Other observations

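The comparisons and the tests of explanations in this part were all chosen after the results had been seen. The endothelial-like clusters of set 1 differed in more than interferon genes, and values here are relative to the median of all genes between them, which was 0.18 over 5138 genes. Arterial genes were higher in cluster 2 in 9 of 12 members and lower in none, with a median of 1.60 (0.94 to 1.85), and the chemokine receptor CXCR4 had a ratio of 11.8. Endothelial genes were higher in 10 of 37, with a median of 0.72 (0.61 to 0.90). Pluripotency genes were lower in cluster 2 in 3 of 15 and higher in none, with a median of −0.79 (−1.10 to −0.23), and POU5F1 stood at 29.7 CPM in cluster 2 and 100.9 CPM in cluster 5. G2/M genes were lower in 24 of 26 (median −1.54, −1.73 to −1.30) and S phase genes in 10 of 25 (median −0.93), with TOP2A at a ratio of 0.285 and CENPF at 0.292. The highest ratios belonged to PSMB8 (39.1, 17.8 to 107.3), CMPK2 (26.3), TAP1 (25.4), XAF1 (16.8) and SLFN5 (15.9), and the lowest to NTS (0.222) and RARRES2 (0.225).

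The early embryo cluster also differed from the other cells of its library, by 0.12 in the median of 999 genes, and values are relative to it. G2/M genes were lower in 8 of 26 (median −0.73, −1.15 to −0.59), fibroblast genes were lower in 5 of 30, and none of 22 pluripotency genes was higher or lower. The cluster held only 346204 UMIs, and the ratios of 9 fibroblast and 3 pluripotency genes were bounds. Genes without a call there may thus still differ. TMEM185A had a ratio of 12.5 and ZNHIT6 of 8.55, while UNC5B (0.145), ISG15 (0.200) and ACTA2 (0.233) were lower. KHDC1L was counted 260 times in the cluster and 7 times in the rest of the library, MBD3L2 242 and 7 times and RFPL4B 119 and 24 times.

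A cluster of set 2 that the markers named hiPSC-like was led by interferon-induced genes. It held 49 control cells (2.16% of that library) and 17 cells of the library labelled SOX9-induced (0.529%), whose LUM level of 50.5 CPM, against 0 UMIs in the control cells, goes against that name. Its leading genes included IFIT1 at 2881, IFIT2 at 1311, the chemokine CCL5 at 576.3 and the interferon IFNL1 at 101.5 CPM, and IFNB1 had 0 UMIs. What set these genes off was not tested. The interferon-stimulated genes of the flagged part summed to 1234 CPM there and to 1218 CPM in the larger unnamed cluster, which held 19.8% of the library labelled SOX9-induced, against under 300 CPM in each of the other clusters of set 2. Between the libraries 5 of 14 were higher and 2 lower in the one labelled SOX9-induced, with a median of 0.28 (−0.97 to 1.78).

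The SOX9 transcript was not higher in the library labelled SOX9-induced, and explanations for this were tested. If both libraries carried each other's label, pluripotency genes would be higher in this library, and their median of −3.13 (−3.58 to −2.14) argues against it. If it held cells induced with ETV2 or NKX3-2, these would be near their level in set 1, and the larger of both reached 0.560% of it (0.367% to 0.829%), which argues against that as well. A SOX9 transgene that the counting does not see may still be on, and this cannot be told apart from a lack of SOX9 induction. The cartilage targets of SOX9 had a median of 1.74 (−2.41 to 3.82), with an interval that spans 0 and holds the medians of fibroblast-like (1.96) and unnamed cells (1.66). The unnamed cells are a weak comparator, as a SOX9 UMI was found in 9.76% of them after thinning to 5000 UMIs. The fall of pluripotency genes shows that the library differs from uninduced hiPSCs, but not which factor was on. Of these targets 6 of 11 rose and 3 fell, against 2 of 9 and none in the background (median 0.52).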
